A study of Rattus norvegicus with 35 samples.

How the data were processed

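The study measured gene expression on 35 Agilent one-colour rat arrays, 1 per animal, in lung accessory lobes of 6 groups made of 2 genotypes and 3 exposures. Per the labels, lobes were kept in RNAlater, RNA integrity numbers were above 6.90, and 100 ng of RNA was labelled with Cy3. The scanner files hold background-corrected processed signal as an intensity on a linear scale for each spot, made with Feature Extraction 12.0.1.1 per the submitters' processing notes. The authors' matrix holds log2 values for 11555 probes, each centred on its median over the arrays within 0.001, and its column medians ran from -0.083 to 0.069. The filter that led to those 11555 probes is not given in the sources used here. Of these probes 11545 were among the non-control probes of the scanner files, and within an array the 2 sets of values correlated at r = 0.995 to 0.999 with slopes from 0.994 to 1.003. All 35 columns were mapped to a sample (0 left over), and no array had values identical to another's. Slide and scan day were taken per the file headers.

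Values were computed from the 62976 spots per array. The 4259 control spots were left out and spots marked by the scanner software as outliers, 221 to 699 per array, were set to missing. Intensities were taken to log2 and the 75th percentile of each array was subtracted; before that step the percentile ran from 9.63 to 11.1 (median 10.4). Spots of the same probe were averaged, which gave 45598 probes and 34766 gene names. A gene was represented by its probe with the highest mean over all arrays, so 7170 of the genes kept had a choice of probe. Genes were kept where the probe was well above background on at least 5 arrays and measured on at least 3 per group. This left 24468 genes with 150 missing values, 15214 of them with a gene symbol; other names are clone or probe identifiers. The accession of 21215 probes was found in the reference table of rat genes, which was used for names only.

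All genes were fitted in 1 linear model with a mean per group, in R 4.3.3 with limma 3.58.1 (empirical Bayes); data.table was version 1.17.8. P-values were adjusted by the method of Benjamini and Hochberg within each comparison, with a threshold of 0.05. Values after ± are limma's standard errors, except for list scores, where they come from an ordinary linear model. Adjusted p without another name is limma's. The comparisons were each nanotube against control and Mitsui-7 against NM-403 within each genotype, p53het against WT controls, and the interaction of genotype with each nanotube. Lists of genes, 15 for pathways and 19 for cell types, were tested with camera at a preset correlation of 0.01 where at least 4 members were measured. Camera asks whether a list is shifted against the other genes. Camera with an estimated correlation and fry, which asks whether a list's genes move on balance one way, were run as alternatives. Counts of list members refer to adjustment over all genes unless the text says adjusted over the list alone.

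The groups, comparisons, lists, thresholds and rule for named genes were set before the data were examined. For each comparison the rule named the 10 genes with the largest rise and the 10 with the largest fall among called genes with a symbol that were well above background on every array of the higher group. It also named up to 4 called members of each list and, always, genes that include Cdkn1a and Mdm2; some of the genes named by the rule are not reported here, and genes outside the rule are marked as such. Members that moved against their list were added after their values were seen. Where no array of a group had a gene above background, its fold is given only as a bound. For the bound each array of that group was set to the higher of its own value and its lowest value well above background.

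Slide as a block was set as an alternative before the data were examined. Residuals of arrays on the same slide correlated more (mean r 0.239 over 99 pairs) than those of other pairs (-0.056 over 411). Differences within slides used the group means of each slide on which both groups lay. Replicate numbers do not pair the arrays: pairs with the same number had a mean r of 0.03, from -0.574 to 0.693. The overlap of comparisons with shared controls was set against 100 simulated draws without any effect and against splits of the controls. Methods were tested on simulated data with the means and spreads of the real genes, a part of them changed by known folds. For each comparison 67 of 24468 genes were changed 1.5-fold, 67 2-fold and 66 4-fold. Noise was drawn independently for each gene and array, without slide effects, so the shares recovered need not hold for the real data. In a further simulation, with a shared effect on every gene, a covariance of 0.0888 between 2 comparisons with shared controls was recovered as 0.0845.

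Alternatives were quantile normalization, the array median for scaling, normexp background correction with an offset of 50, the authors' values, stricter and no filters, the mean of all probes, array weights, slide as a fixed or random block (correlation 0.354), a replicate block, models of only the groups compared, other thresholds, and leaving out each array in turn. Leaving out 2 arrays together was added after seeing the data. Up to 100 splits of the arrays were drawn for each comparison, and for the 6 comparisons with calls all splits within slides were run, added after seeing the data. RNA integrity per array and any histology were not used here. Precision is limited by the number of arrays.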

Results

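Gene expression was measured in the accessory lung lobe of 35 female Sprague Dawley rats, with 1 one-colour array per rat. The rats were wild type (WT) or, in the groups labelled GMO, heterozygous for p53 (p53het). They received 4 weekly instillations into the trachea of vehicle, Mitsui-7 or NM-403, and the lobe was taken 3 days after exposure. Mitsui-7 and NM-403 are multi-walled carbon nanotubes. The labels give 0.25 mg per rat without saying whether that was each instillation or the total. There were 6 rats in each group except p53het NM-403, which had 5.

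Each array carried 58717 spots outside the controls, of which 66.1% to 86.4% were well above background (median 71.5%), and no such spot was saturated. The arrays lay on 5 slides, and each group was spread over 4 or 5 of them. After the group means were removed, arrays on the same slide correlated at a mean r of 0.239, against -0.056 for arrays on different slides. The main model has no term for slide; models with slide as a block and values within slides are given beside it. The number of arrays limits the precision of every fold change.

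WT Mitsui-7 against WT control asks what this nanotube changed in rats with both p53 alleles. Spp1, which encodes the secreted glycoprotein osteopontin, rose 77.3-fold (log2 6.27 ± 0.30, adjusted p = 9.13e-16, 6 rats per group). Mt3, a metallothionein, rose 49.6-fold (5.63 ± 0.33, adjusted p = 2.06e-13). Clca1, a secreted product of mucous cells, rose 31.7-fold (4.99 ± 0.48). Mmp7, a matrix metalloproteinase, rose by 5.71 ± 0.66 on the log2 scale, with only 2 of 6 control arrays above background. Il24 rose by 4.43 ± 0.31, with 3 of 6 controls above background. Cd5l rose at least 12.1-fold (limma adjusted p = 2.34e-08) and Sctr, the secretin receptor, at least 11.2-fold (limma adjusted p = 1.82e-12), each at background on all 6 control arrays. Cxcl11, a chemokine induced by interferon, rose at least 8.83-fold (limma adjusted p = 1.36e-09) and Slc1a6 at least 5.25-fold (limma adjusted p = 5.85e-10) on the same terms. Itln1 rose by 6.14 ± 1.67 (adjusted p = 0.0115), but only 4 of the 6 exposed rats lay above every control.

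The falls in WT Mitsui-7 lungs were smaller. Npr3, the clearance receptor for natriuretic peptides, fell 3.44-fold (log2 -1.78 ± 0.27, adjusted p = 1.98e-05). Cyp2a3, a cytochrome P450, fell 2.92-fold (-1.54 ± 0.36, adjusted p = 0.0028). Ahrr, the repressor of the aryl hydrocarbon receptor, fell by 1.30 on the log2 scale (SE 0.29) and Aox1 by 1.36 (SE 0.33). The cardiac gene Lrrc10 fell at least 1.52-fold (limma adjusted p = 0.000136) and was at background on all 6 exposed arrays. Zbtb16 fell by 1.52, Bpifa1 by 1.88 and RT1-O1 by 2.02 on the log2 scale. Of the genes tied to p53, Cdkn1a rose 1.60-fold (0.68 ± 0.12, adjusted p = 8.78e-05), while Mdm2 (0.30 ± 0.11, adjusted p = 0.0517) did not pass.

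Among inflammatory lists in WT Mitsui-7 lungs, 11 of 28 chemokine ligands rose and Ccl6, Ccl20, Cxcl1 and Cxcl14 fell, with Cxcl10 up 12.8-fold (3.67 ± 0.30) and Ccl7 up 5.22-fold (2.39 ± 0.31); the median was 0.42 (camera adjusted p = 0.000495). That list lost its call at adjusted p = 0.0751 with an estimated correlation. Inflammatory cytokines did not pass as a list in the main model (median 0.18, camera adjusted p = 0.0752) but did with quantile normalization (0.0276), the authors' values (0.021) and in fry (1.11e-05); Il1rn rose by 2.25 ± 0.16 and Csf2 fell by 0.32. In the type 2 response list 5 of 18 members rose and Il4r fell by 0.49, with Retnla up 9.15-fold and Agr2 up 5.14-fold (median 0.71, camera adjusted p = 0.000495). Acute phase proteins rose for 5 of 13 members, among them A2m by 3.37 ± 0.26 and Serpina3n by 1.70 (median 0.28, camera adjusted p = 0.00183), but the list had adjusted p = 0.117 with an estimated correlation. The NF-kB, Toll-like receptor and inflammasome list had 5 of 18 members higher, including Aim2 (1.23) and Cd14 (1.20), and Icam1 lower, with a camera adjusted p = 0.0357 and adjusted p = 0.117 with an estimated correlation. Of 23 interferon-stimulated genes 10 rose, such as Ifit3 (1.47 ± 0.27), Usp18 (1.32 ± 0.20) and Mx1 (1.30 ± 0.19), with a median of 0.39 (camera adjusted p = 4.31e-07, adjusted p = 0.0898 with an estimated correlation). Complement rose for 9 of 18 members, with C3ar1 at 1.51 ± 0.13 and C1qa at 1.09 (median 0.40, camera adjusted p = 2.89e-08). MHC class II presentation rose for 5 of 9 members, among them Cd86 (1.57 ± 0.18) and RT1-Bb (1.03), with a median of 0.50 (camera adjusted p = 5.94e-06, adjusted p = 0.0751 with an estimated correlation).

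Matrix, mitotic, DNA repair and lysosome lists rose in the same WT rats, while the p53 and clock lists did not pass. In the extracellular matrix and remodelling list 17 of 35 members rose and none fell, with Mmp12 up 17.8-fold (4.16 ± 0.26) and Mmp9 up by 2.86 ± 0.34 (median 0.46, camera adjusted p = 2.82e-12). The mitotic cell cycle list had the strongest shift of the 34 lists: 33 of 35 members rose and the other two did not pass, with Aurkb at 1.87 ± 0.36, Ccne1 at 1.77 ± 0.18 and a median of 1.34 (camera adjusted p = 6.41e-37). DNA repair genes rose for 9 of 28 members, such as Exo1 (1.24 ± 0.13) and Fanca (1.04), with a median of 0.23 (camera adjusted p = 0.00296). The lysosome and macrophage lipid handling list rose for 14 of 27 members, with Ctsk up 7.41-fold and Trem2 up 4.59-fold, and had a median of 0.55 (camera adjusted p = 3.94e-08, adjusted p = 0.0614 with an estimated correlation). NRF2 and oxidative stress genes passed or not depending on the model (median 0.14): camera adjusted p = 0.0966 in the main model, 0.0399 with slide as a fixed block, 0.0479 with slide as a random block, 0.0125 with quantile normalization and 0.0348 with the authors' values, and fry adjusted p = 0.0122. Slc7a11, the cystine transporter, rose 11.6-fold (3.53 ± 0.29) and Sod3 fell by 0.62. The p53 targets did not shift (28 members, median -0.02, mean 0.04, camera adjusted p = 0.828): Cdkn1a, Pmaip1 (0.70) and Ccng1 (0.31) rose and Gadd45a fell by 0.35. Circadian clock genes did not pass as a list either (median -0.13, camera adjusted p = 0.444), and Bhlhe41 alone rose (1.05).

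Markers of leukocytes in WT Mitsui-7 lungs rose for some cell types only. Macrophage and monocyte markers rose for 8 of 15 members, with Itgam up 5.09-fold and Ms4a7 by 1.61 (median 0.81, camera adjusted p = 2.15e-05). Plasma cell markers rose for 6 of 8 members, with Jchain at 1.48 ± 0.30 and Mzb1 at 1.28 (median 0.89, camera adjusted p = 1.39e-05). Mast cell markers had 4 of 10 members higher and Kit lower, with Mcpt2 at 1.79 and Cpa3 at 1.07 (median 0.96, camera adjusted p = 0.0438, adjusted p = 0.358 with an estimated correlation). Dendritic cell markers rose for 3 of 9 members, such as Cd83 (1.05), with a camera adjusted p = 0.00966 and adjusted p = 0.0803 with an estimated correlation. T cell markers rose for 3 of 16 members, among them Icos (0.89) and Cd4 (0.51), with a median of 0.17 (camera adjusted p = 0.0438, adjusted p = 0.4 with an estimated correlation). Neutrophil markers did not pass (camera adjusted p = 0.833), and their median of 0.14 and mean of 0.04 lay above 0 while the test pointed lower; Fpr1 fell by 0.81 and Selplg rose by 0.45. Eosinophil (camera adjusted p = 0.764), NK cell (0.764) and B cell markers (0.71) did not pass as lists.

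Structural cell markers in WT Mitsui-7 lungs went both ways. Ciliated cell markers rose for 7 of 13 members, such as Dynlrb2 (0.84) and Tekt1 (0.80), with a median of 0.54 (camera adjusted p = 2.91e-05, adjusted p = 0.0803 with an estimated correlation). Club and secretory cell markers did not pass in camera (adjusted p = 0.475) but did in fry (adjusted p = 0.000831), and their median of -0.23 had the opposite sign to their mean of 0.66: Muc5b rose by 4.42 ± 0.46 (2 of 6 controls above background) and Bpifb1 9.78-fold, while Cyp2f4 fell by 0.55. Endothelial cell markers fell for 8 of 12 members, with Tek at -0.85 ± 0.13 and Ramp2 at -0.79 ± 0.10 (median -0.63, camera adjusted p = 4.57e-09). Alveolar type 1 cell markers fell for 4 of 9 members, with Cav1 at -0.47 and Aqp5 at -0.39 (median -0.33, camera adjusted p = 6.97e-05). Alveolar type 2 cell (camera adjusted p = 0.485), smooth muscle cell (0.764) and adipocyte markers (0.325) did not pass. Mesothelial cell markers fell for 3 of 8 members, Upk1b at -1.09 ± 0.17, Bnc1 at -0.78 and Upk3b at -0.73, whereas Msln rose by 0.64 ± 0.12; the median was -0.46 (camera adjusted p = 0.00366, adjusted p = 0.108 with an estimated correlation). Erythroid markers fell for 5 of 9 members, with Hba-a1 at -1.01 (median -0.76, camera adjusted p = 1.97e-05, adjusted p = 0.108 with an estimated correlation). Cardiac muscle markers fell for 6 of 10 members, with Myh6 at -1.11 ± 0.24 (median -0.78, camera adjusted p = 4.02e-06, adjusted p = 0.0982 with an estimated correlation).

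Over all genes, 3418 of 24468 passed at adjusted p under 0.05 in WT Mitsui-7 lungs, 2058 higher and 1360 lower, and 1976 of these changed at least 1.5-fold. The share of higher calls depended on the scaling: it was 60.2% with the 75th percentile, 44.3% with quantile normalization (1649 higher, 2075 lower), 43.1% with the array median and 37.3% with the authors' values. With slide as a fixed block 5430 genes passed, of which 3388 were among the 3418. Of genes called with a slide left out, 94.4% to 97.7% had the same direction on that slide (4 slides). The list medians within slides ran from 0.99 to 1.46 for the mitotic list, 0.45 to 0.62 for extracellular matrix, 0.22 to 0.81 for interferon-stimulated genes, -1.07 to -0.39 for endothelial markers, -0.86 to -0.14 for mesothelial markers and -0.92 to -0.76 for cardiac markers. In a simulation of this comparison, with independent noise and few changed genes, 46.3% of genes changed 1.5-fold and 95.5% of those changed 4-fold were recovered.

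**Figure D1:**
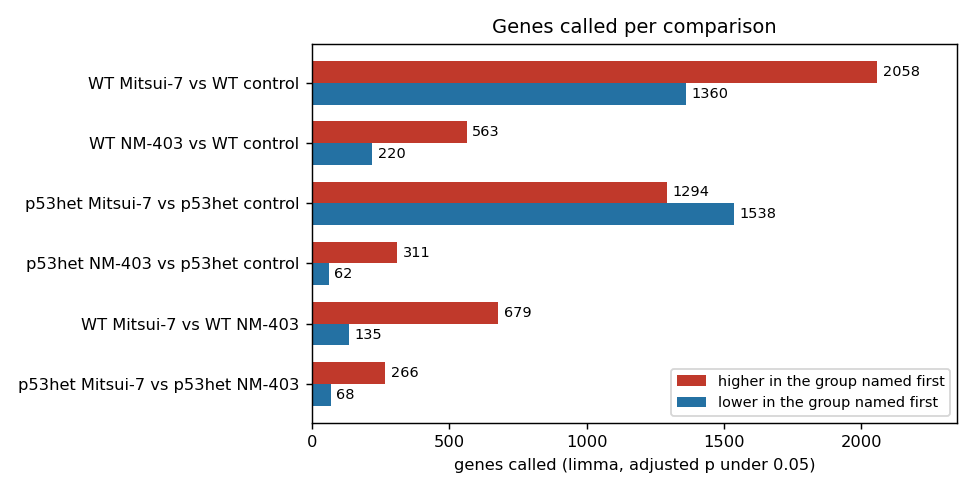
Genes called by limma at adjusted p under 0.05 in each of 6 comparisons, as the number of genes higher (red) or lower (blue) in the group named before "vs". In this model WT Mitsui-7 lungs had the most, 2058 higher and 1360 lower; p53het Mitsui-7 lungs had more with slide as a fixed block (5521 against 5430), array weights (5239 against 4041) and without 2 arrays (3439 against 2867).

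WT NM-403 against WT control asks the same of the second nanotube. Spp1 again rose most, 17.3-fold (4.11 ± 0.30, adjusted p = 1.83e-10, 6 rats per group). Retnla, a secreted product of alternatively activated macrophages, rose 6.37-fold (2.67 ± 0.38, adjusted p = 4.61e-05). Orm1, an acute phase glycoprotein, rose 6.03-fold (2.59 ± 0.46, adjusted p = 0.000671). Mmp12 rose 5.43-fold (2.44 ± 0.26), Muc4 5.42-fold (2.44 ± 0.34), Tnn 7.42-fold (2.89 ± 0.40) and Dhrs9 4.94-fold (2.30 ± 0.24). Mmp7 rose by 3.50 ± 0.66 and Gsg1 by 2.98 ± 0.40 with 2 of 6 control arrays above background, and Ccl1 by 2.63 ± 0.46 with 3 of 6. The largest falls were in Sytl5 (-1.56 ± 0.29, with 2 of 6 exposed arrays above background), the neuropeptide gene Tac1 (-1.40 ± 0.31) and Ucp3 (-1.38 ± 0.34). Fbp1 fell by 1.29, Wnt2b by 1.19 and Npr3 by 0.97 on the log2 scale. Cdkn1a (0.11 ± 0.12, adjusted p = 0.749) and Mdm2 (0.10, adjusted p = 0.762) did not pass.

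The list with the strongest shift under NM-403 in WT rats was again the mitotic cell cycle, with 29 of 35 members higher, Ccne1 at 1.5 ± 0.18 and Bub1b at 1.27 (median 0.95, camera adjusted p = 8.6e-49). Acute phase proteins followed, with 8 of 13 members higher, Lcn2 at 1.52 ± 0.28 and Hpx at 1.26 (median 0.82, camera adjusted p = 1.8e-17). Complement rose for 3 of 18 members, C3 (0.96 ± 0.17), Cfi (1.14) and Cfb (0.67), and for 10 when adjusted over the list alone (median 0.40, camera adjusted p = 5.94e-09). Chemokine ligands rose for 4 of 28 members, among them Ccl7 (2.16 ± 0.31) and Ccl2 (1.62 ± 0.31), with a camera adjusted p = 2.23e-05. Inflammatory cytokines rose for 2 of 15 members, Il12b (1.54, with 2 of 6 controls above background) and Il1rn (1.11), with a camera adjusted p = 0.00285. DNA repair rose for 4 of 28 members, such as Exo1 (1.11) and Fanca (0.92), with a camera adjusted p = 3.37e-05. Plasma cell markers rose for 4 of 8 members, with Jchain at 1.31 and Derl3 at 1.19 ± 0.16 (median 0.70, camera adjusted p = 2.57e-07). Mesothelial cell markers fell for 4 of 8 members, Upk1b at -0.91, Wt1 at -0.89, Bnc1 at -0.68 and Upk3b at -0.49 (median -0.42, camera adjusted p = 7.46e-05).

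A further 8 lists passed in WT NM-403 lungs with the preset correlation only. Neutrophil markers rose for 4 of 14 members, Il1r2 at 2.15 ± 0.28 and S100a9 4.20-fold among them (camera adjusted p = 7.46e-05, adjusted p = 0.0589 with an estimated correlation). The lysosome list rose for 6 of 27 members, such as Trem2 at 1.64 (camera adjusted p = 2.53e-05, adjusted p = 0.154 with an estimated correlation). Extracellular matrix rose for 6 of 35 members around a median of 0.01 and a mean of 0.39 (camera adjusted p = 0.00782, adjusted p = 0.302 with an estimated correlation). The NRF2 list rose for 4 of 25 members, Slc7a11 at 1.38 ± 0.29 the most (camera adjusted p = 0.00441, adjusted p = 0.234 with an estimated correlation). The type 2 list rose for 3 of 18 members (camera adjusted p = 0.0225, adjusted p = 0.0604 with an estimated correlation). MHC class II had no member past the threshold over all genes and 3 of 9 higher adjusted over the list alone (camera adjusted p = 0.00308, adjusted p = 0.27 with an estimated correlation). Endothelial markers likewise had none over all genes and 3 of 12 lower adjusted over the list alone (median -0.33, camera adjusted p = 2.53e-05, adjusted p = 0.0837 with an estimated correlation). Alveolar type 1 markers had 1 of 9 lower, Cav1 at -0.48 (camera adjusted p = 0.000144, adjusted p = 0.0589 with an estimated correlation). The p53 targets (median 0.03, camera adjusted p = 0.401) and cardiac markers (median -0.18, camera adjusted p = 0.323) did not pass. Macrophage and monocyte markers passed only under alternatives, with camera adjusted p = 0.0409 with slide as a fixed block, 0.038 as a random block and 0.0112 with the authors' values. Interferon-stimulated genes (0.0409 and 0.038) and alveolar type 2 markers (0.028 and 0.038) passed in camera with the same 2 slide blocks but not in the main model.

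Of 24468 genes, 783 passed in WT NM-403 lungs, 563 higher and 220 lower, and 448 changed at least 1.5-fold. The share higher, 71.9%, was 56.7% with slide as a fixed block (1072 higher, 820 lower) and 58.4% with array weights. Without WT_NM403 replicate 6 the number fell to 459. Blocking on slide gave 1892 genes, including all 783. On a slide left out, 89.1% to 100% of the genes called on the others kept their direction (5 slides). Within slides the list medians ran from 0.53 to 1.30 for the mitotic list, 0.50 to 1.04 for acute phase proteins and -0.74 to -0.06 for mesothelial markers, while cardiac markers ran from -0.82 to 0.41. The simulation recovered 41.8% of genes changed 1.5-fold and 97.0% of those changed 4-fold.

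p53het Mitsui-7 against p53het control asks what Mitsui-7 changed in rats with the altered allele. Spp1 rose 94.8-fold (6.57 ± 0.30, adjusted p = 3.09e-16, 6 rats per group) and Mt3 54.5-fold (5.77 ± 0.33, adjusted p = 7.82e-14). Clca1 rose 45.9-fold (5.52 ± 0.48) with 4 of 6 controls above background, as did Mmp7 21.2-fold (4.41 ± 0.66). Il24 rose by 4.88 ± 0.31 with 2 of 6 controls above background, the mucin gene Muc5b by 4.24 ± 0.46 with 1 of 6, and Foxn4 by 3.92 ± 0.26 with 3 of 6. Cxcl11 rose at least 5.98-fold (limma adjusted p = 1.19e-08), Reg3b at least 5.25-fold (limma adjusted p = 5.62e-07) and Sctr at least 4.37-fold (limma adjusted p = 5.81e-10). The largest falls were in Mlc1 (at least 3.60-fold, limma adjusted p = 0.000276), Cyp2a3 (5.42-fold, -2.44 ± 0.36, with 4 of 6 exposed arrays above background) and Car12 (-2.41 ± 0.51). Fam107a fell by 2.05, Ucp3 by 2.01 and the endothelial gene Esm1 by 1.90 on the log2 scale. Cdkn1a rose 1.58-fold (0.66 ± 0.12, adjusted p = 0.000192), and Mdm2 (0.10, adjusted p = 0.617) did not pass.

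In p53het Mitsui-7 lungs 32 of 35 mitotic cell cycle genes rose, with Aurkb at 1.94 and Ccne1 at 1.57 (median 1.05, camera adjusted p = 6.85e-35). The extracellular matrix list rose for 17 of 35 members, with Mmp12 up 12.8-fold (3.68 ± 0.26) and Thbs2 by 2.16 (median 0.47, camera adjusted p = 1.76e-15). Complement rose for 12 of 18 members, such as C6 (1.96) and Cfi (1.28), with a median of 0.48 (camera adjusted p = 3.27e-12). Chemokine ligands had 12 of 28 members higher and Ccl5, Ccl6 and Ccl21 lower, with Ccl7 up 8.08-fold (3.02 ± 0.31) and Cxcl10 6.69-fold (2.74 ± 0.30) (camera adjusted p = 2.43e-06). The type 2 list had 6 of 18 members higher, including Retnla (3.11 ± 0.38) and Agr2 (2.07), and Il4r lower (camera adjusted p = 1.38e-05). Acute phase proteins rose for 5 of 13 members, with A2m up 9.02-fold (camera adjusted p = 4.15e-07). The lysosome list rose for 13 of 27 members, Ctsk 8.10-fold and Fabp4 by 3.15 ± 0.29 (camera adjusted p = 2.69e-10). Plasma cell markers rose for 6 of 8 members, with Jchain at 1.47 (camera adjusted p = 3.17e-07). Macrophage and monocyte markers rose for 4 of 15 members, with Itgam at 2.07 ± 0.22 (camera adjusted p = 0.00204). DNA repair rose for 5 of 28 members, such as Fanca (1.04) (camera adjusted p = 0.0166). Endothelial markers fell for 8 of 12 members, with Tek at -0.87 and Ramp2 at -0.81 (median -0.61, camera adjusted p = 3.34e-08).

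Another 10 lists in p53het Mitsui-7 lungs passed with the preset correlation only. Cardiac muscle markers fell for 7 of 10 members, with Ryr2 at -1.17 and Mybpc3 at -0.99 (median -0.82, camera adjusted p = 3.48e-06, adjusted p = 0.107 with an estimated correlation). Alveolar type 1 markers fell for 4 of 9 members (camera adjusted p = 0.000937, adjusted p = 0.0827 with an estimated correlation). NK cell markers fell for 2 of 10 members, Prf1 (-0.69) and Gzma (-0.58) (camera adjusted p = 0.00449, adjusted p = 0.304 with an estimated correlation). B cell markers fell for 1 of 11 members (median -0.36, camera adjusted p = 0.0145, adjusted p = 0.232 with an estimated correlation). Erythroid markers fell for 1 of 9 members, Hbb at -0.57 (camera adjusted p = 0.0211, adjusted p = 0.415 with an estimated correlation). MHC class II rose for 4 of 9 members, such as Cd86 at 1.38 (camera adjusted p = 0.000192, adjusted p = 0.132 with an estimated correlation). Ciliated markers had 5 of 13 higher and Tppp3 lower (camera adjusted p = 0.00353, adjusted p = 0.232 with an estimated correlation). Dendritic markers had 3 of 9 higher and Zbtb46 lower, which a second probe did not show at 0.13 (camera adjusted p = 0.0131, adjusted p = 0.0829 with an estimated correlation). Inflammatory cytokines had 2 of 15 higher, Il1rn at 2.28 ± 0.16 and Csf1 at 0.64, and Il33 lower at -0.40 (camera adjusted p = 0.0259, adjusted p = 0.0788 with an estimated correlation). Mast cell markers had 5 of 10 higher, and Kit and Gata2 lower (camera adjusted p = 0.0297, adjusted p = 0.322 with an estimated correlation).

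Lists that did not pass in p53het Mitsui-7 lungs included interferon-stimulated genes (median 0.09, camera adjusted p = 0.302), of which Usp18 alone rose (0.61 ± 0.20), and the p53 targets (median 0.02, camera adjusted p = 0.54), of which Cdkn1a rose and Gadd45a fell by 0.48. Mesothelial markers did not pass either (median 0.09, camera adjusted p = 0.54): Msln rose by 1.12 ± 0.12 while Gpm6a fell by 0.72 and Bnc1 by 0.54, although a second Bnc1 probe read 0.01. NRF2 and oxidative stress genes passed only under alternatives. Their camera adjusted p was 0.0229 with slide as a fixed block, 0.0316 as a random block and 0.0218 with array weights. Over all genes 2832 passed, 1294 higher and 1538 lower, and 1514 changed at least 1.5-fold, 908 of them higher. The share higher, 45.7%, turned to 55.3% with the array median, 52.5% with the authors' values, 54.5% in a model of only the groups compared and 53.7% without the 2 arrays that stood apart, a setting chosen after the data were seen. With slide as a fixed block 5521 genes passed, including 2829 of the 2832. Genes called with a slide left out kept their direction on it for 88.4% to 97.7% (5 slides). Within slides the medians ran from 0.72 to 1.25 for the mitotic list, 0.42 to 0.61 for extracellular matrix, -0.75 to -0.37 for endothelial markers, -1.29 to -0.06 for cardiac markers, -0.22 to 0.21 for mesothelial markers and -0.19 to 0.60 for interferon-stimulated genes. The simulation recovered 46.3% of genes changed 1.5-fold and 95.5% of those changed 4-fold.

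p53het NM-403 against p53het control asks the same of NM-403, with 5 exposed rats and 6 controls. Spp1 rose 17.8-fold (4.15 ± 0.31, adjusted p = 4.97e-10) and Orm1 8.26-fold (3.05 ± 0.48, adjusted p = 0.000315). The chemokine gene Ccl7 rose 5.73-fold (2.52 ± 0.33), Retnla 5.45-fold (2.45 ± 0.40), Upk3bl1 by 2.33 ± 0.39 (4 of 6 controls above background) and Muc4 4.66-fold (2.22 ± 0.36). Gsg1 rose by 2.38 ± 0.42 with 3 of 6 controls above background, and Reg3b, an antimicrobial lectin, rose at least 1.501-fold (limma adjusted p = 0.0168) from background on all 6. Scn10a rose by 2.17 ± 0.34 and Saal1 by 2.15 ± 0.32. Ucp3 fell by 1.45, Sun5 by 1.31, Serpina1 by 1.27, Acoxl by 1.22 and the muscle kinase gene Alpk3 by 1.02 on the log2 scale. Cdkn1a (-0.01, adjusted p = 0.984) and Mdm2 (-0.09, adjusted p = 0.801) did not pass.

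In p53het NM-403 lungs 24 of 35 mitotic genes rose, with Melk and Pbk each at 1.53 (Pbk with 2 of 6 controls above background) and Ccne1 at 1.49 ± 0.19 (median 0.92, camera adjusted p = 8.67e-62). Acute phase proteins rose for 7 of 13 members, Lcn2 at 1.60 ± 0.30 and Hpx at 1.18 (median 0.74, camera adjusted p = 3.07e-16). Complement rose for 5 of 18 members, such as Cfi (1.14) and Cfb (0.80) (camera adjusted p = 1.92e-13). Plasma cell markers rose for 4 of 8 members, with Tnfrsf17 at 1.36 (camera adjusted p = 4.08e-12). MHC class II rose for 1 of 9 members over all genes, Cd86 at 0.88, and for 6 adjusted over the list alone (camera adjusted p = 4.59e-09). DNA repair rose for 4 of 28 members, with Fanca at 1.05 (camera adjusted p = 1.49e-06). Chemokine ligands rose for 3 of 28 members, with Ccl2 at 2.01 ± 0.32 (camera adjusted p = 1.37e-05). Dendritic cell markers rose for 2 of 9 members, with Clec9a at 0.85 (camera adjusted p = 8.2e-05). The type 2 list rose for 4 of 18 members, including Clca1 (2.08 ± 0.51) and Slc26a4 (1.60) (camera adjusted p = 9.96e-05). Inflammatory cytokines rose for 1 of 15 members, Il1rn at 1.09 (camera adjusted p = 0.00635).

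The other 9 lists that passed in p53het NM-403 lungs did so with the preset correlation only. Neutrophil markers rose for 2 of 14 members, Il1r2 (1.74) and S100a9 (1.60 ± 0.32) (camera adjusted p = 0.00391, adjusted p = 0.178 with an estimated correlation). The NRF2 list rose for 1 of 25 members, Slc7a11 at 1.99 ± 0.31 (camera adjusted p = 0.0027, adjusted p = 0.186 with an estimated correlation). The lysosome list had no member past the threshold over all genes and 4 of 27 adjusted over the list alone (camera adjusted p = 0.000169, adjusted p = 0.186 with an estimated correlation). Macrophage and monocyte markers had a median of -0.04, below 0, but a mean of 0.21 and a test that pointed higher (camera adjusted p = 0.0466, adjusted p = 0.186 with an estimated correlation). Alveolar type 1 markers fell for 2 of 9 members, Rtkn2 (-0.57) and Cav1 (-0.44) (camera adjusted p = 0.000169, adjusted p = 0.0502 with an estimated correlation). Mesothelial markers fell for 1 of 8 members, Upk3b at -0.63 (median -0.35, camera adjusted p = 0.00263, adjusted p = 0.124 with an estimated correlation). Endothelial markers had none lower over all genes and 3 of 12 adjusted over the list alone (camera adjusted p = 0.000565, adjusted p = 0.178 with an estimated correlation). Alveolar type 2 markers were shifted up (median 0.17, camera adjusted p = 0.0149, adjusted p = 0.356 with an estimated correlation) and cardiac markers down (median -0.39, camera adjusted p = 0.0363, adjusted p = 0.489 with an estimated correlation) with no member past the threshold. The p53 targets (median 0.00, camera adjusted p = 0.195) and interferon-stimulated genes (median 0.03, camera adjusted p = 0.41) did not pass, but with normexp background correction both did (0.0193 and 0.0416).

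Over all genes 373 passed in p53het NM-403 lungs, 311 higher and 62 lower, and 299 changed at least 1.5-fold. The share higher was 83.4%, but 67.5% with normexp background correction, 56.8% with slide as a fixed block and 40.2% with array weights (961 higher, 1432 lower). Leaving out p53het_NM403 replicate 1 gave 618 calls, replicate 2 gave 227, replicate 3 gave 234 and replicate 5 gave 231. Blocking on slide gave 960 genes, including all 373. With a slide left out, 85.7% to 100% of the genes then called kept their direction on it (4 slides). Within slides the medians ran from 0.62 to 1.38 for the mitotic list, 0.50 to 0.74 for acute phase proteins, 0.17 to 0.51 for complement and -0.56 to -0.21 for mesothelial markers. The simulation recovered 37.3% of genes changed 1.5-fold and 97.0% of those changed 4-fold.

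**Figure D2:**
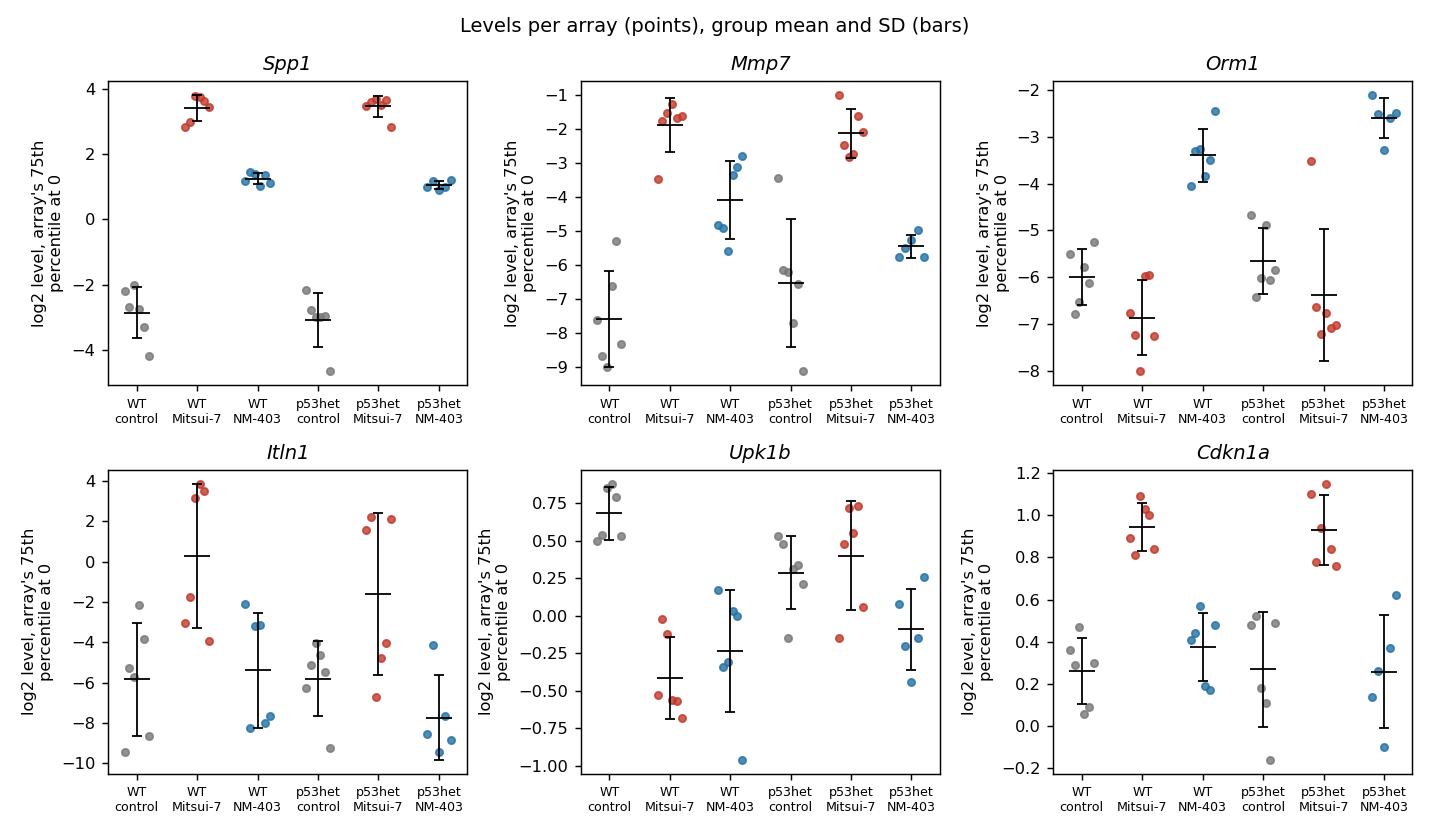
Log2 levels of 6 genes on each array (points) with group means and SD (bars), the 75th percentile of each array at 0. Spp1 was higher in every exposed rat than in every control, and Cdkn1a was called higher with Mitsui-7 in both genotypes.

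WT Mitsui-7 against WT NM-403 asks which genes set the 2 nanotubes apart at the same stated dose. Spp1 was 4.48-fold higher with Mitsui-7 (2.16 ± 0.30). Clca1 was 15.0-fold higher (3.91 ± 0.48, adjusted p = 2.17e-06), Muc5b by 3.68 ± 0.46 on the log2 scale (3 of 6 NM-403 arrays above background) and Mt3 10.2-fold (3.34 ± 0.33, adjusted p = 4.62e-08). At background on all 6 NM-403 arrays, Cd5l was at least 10.1-fold higher (limma adjusted p = 2.65e-06), Sctr at least 9.37-fold (limma adjusted p = 3.78e-10) and Mmp3 at least 4.98-fold (limma adjusted p = 1.25e-09). Orm1 was lower with Mitsui-7 (log2 -3.46 ± 0.46, adjusted p = 7.05e-06, 4 of 6 Mitsui-7 arrays above background) and the neutrophil gene S100a9 was 6.52-fold lower (-2.70 ± 0.30, adjusted p = 4.44e-07). Lpo, a peroxidase of airway secretions, was lower by 2.43 ± 0.29, Cxcl6 by 2.37 ± 0.49 and Hpx by 1.56 ± 0.22. Cdkn1a was higher with Mitsui-7 (0.57 ± 0.12, adjusted p = 0.00269), and Mdm2 (0.20, adjusted p = 0.41) did not pass.

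Extracellular matrix genes were higher with Mitsui-7 in WT rats for 13 of 35 members, with Mmp9 at 2.06 and Mmp12 at 1.72 (median 0.48, camera adjusted p = 3.5e-16). Macrophage and monocyte markers were higher for 6 of 15 members, with Itgam at 1.31, and lower for Chi3l1 at -1.01 (median 0.40, camera adjusted p = 2.59e-05). The other 15 lists that passed did so with the preset correlation only. Interferon-stimulated genes were higher for 5 of 23 members, Mx1 (1.02) and Irf7 (1.00) among them (median 0.39, camera adjusted p = 1.14e-07, adjusted p = 0.113 with an estimated correlation). Acute phase proteins had 5 of 13 lower, such as Lcn2 (-1.33), and 2 higher, such as A2m (2.13) (median -0.33, camera adjusted p = 0.000161, adjusted p = 0.113 with an estimated correlation). Neutrophil markers were lower for 3 of 14 members (median -0.20, camera adjusted p = 1.67e-05, adjusted p = 0.0977 with an estimated correlation). Mast cell markers were higher for 4 of 10 members, Ms4a2 at 1.53 (median 1.19, camera adjusted p = 0.000908, adjusted p = 0.172 with an estimated correlation). Ciliated markers were higher for 4 of 13 members (median 0.42, camera adjusted p = 2.29e-06, adjusted p = 0.0977 with an estimated correlation). Cardiac markers were lower for 2 of 10 members, Myh6 and Mybpc3 (median -0.61, camera adjusted p = 3.83e-08, adjusted p = 0.0977 with an estimated correlation). The mitotic list was higher for 1 of 35 members, Aurkb (median 0.27, camera adjusted p = 2.77e-05, adjusted p = 0.335 with an estimated correlation). The p53 targets did not pass (median 0.00, camera adjusted p = 0.692).

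Of the remaining lists with a camera call in WT rats, those higher with Mitsui-7 were type 2 response (median 0.18, adjusted p = 0.0977 with an estimated correlation), complement (0.21, adjusted p = 0.455 with an estimated correlation), MHC class II (0.25, adjusted p = 0.181 with an estimated correlation), lysosome (0.15, adjusted p = 0.181 with an estimated correlation) and dendritic cells (0.15, adjusted p = 0.181 with an estimated correlation). Those lower were endothelial (-0.31, adjusted p = 0.113 with an estimated correlation), erythroid (-0.58, adjusted p = 0.172 with an estimated correlation) and alveolar type 2 markers (-0.14, adjusted p = 0.335 with an estimated correlation). Over all genes 814 passed, 679 higher and 135 lower with Mitsui-7, and 581 differed at least 1.5-fold. The share higher was 83.4%, but 69.9% with quantile normalization, 66.4% with the array median and 63.2% with the authors' values. With slide as a fixed block 1538 genes passed, including 802 of the 814, and 92.8% to 96.5% of genes called with a slide left out had the same direction on it (4 slides). Within slides the medians ran from 0.19 to 0.63 for extracellular matrix, 0.29 to 0.99 for macrophage markers, 0.32 to 0.45 for interferon-stimulated genes and -1.21 to 0.02 for neutrophil markers. The simulation recovered 40.3% of genes differing 1.5-fold.

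In p53het rats the same comparison of the nanotubes gave Mt3 16.9-fold higher with Mitsui-7 (4.08 ± 0.35, adjusted p = 4.56e-09, 6 rats against 5), Clca1 10.9-fold (3.44 ± 0.51), Il24 8.03-fold (3.01 ± 0.32) and Mmp7 by 3.33 ± 0.69 on the log2 scale. Muc5b was higher by 3.42 ± 0.49 with 1 of 5 NM-403 arrays above background. Sctr was at least 4.95-fold higher (limma adjusted p = 6.43e-09), Mmp3 at least 3.69-fold (limma adjusted p = 2.68e-07) and Krt17, a keratin of basal and injured epithelium, at least 3.54-fold (limma adjusted p = 1.28e-08). Orm1 was lower with Mitsui-7 (log2 -3.77 ± 0.48, adjusted p = 6.1e-06, 4 of 6 Mitsui-7 arrays above background), S100a9 3.89-fold (-1.96 ± 0.32) and Cyp1a1 at least 3.21-fold (limma adjusted p = 0.0134). Cyp2a3 was lower by 2.33 ± 0.37 and Lpo by 1.83 ± 0.30. Cdkn1a was again higher with Mitsui-7 (0.67 ± 0.12, adjusted p = 0.00118), and Mdm2 (0.19, adjusted p = 0.489) did not pass.

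Extracellular matrix was the one list called in p53het rats with an estimated correlation too: 11 of 35 members were higher with Mitsui-7, with Thbs2 at 1.82 and Mmp12 at 1.61 (median 0.48, camera adjusted p = 5.95e-22). Mesothelial markers were higher for 2 of 8 members, Msln (1.07 ± 0.13) and Upk3b (0.58) (median 0.53, camera adjusted p = 0.000338, adjusted p = 0.166 with an estimated correlation). The lysosome list was higher for 4 of 27 members, Fabp4 at 2.10 (camera adjusted p = 5.86e-07, adjusted p = 0.166 with an estimated correlation). Chemokine ligands were higher for 7 of 28 members, Ccl11 at 1.93 (median 0.00, mean 0.38, camera adjusted p = 0.0247, adjusted p = 0.27 with an estimated correlation). Neutrophil markers were lower for 1 of 14 members (median -0.53, camera adjusted p = 0.00201, adjusted p = 0.2 with an estimated correlation). Acute phase proteins did not pass (2 higher, 2 lower, camera adjusted p = 0.486). The p53 targets (median 0.00, camera adjusted p = 0.652) and the mitotic list (median 0.10, camera adjusted p = 0.608) did not pass either.

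The other lists with a camera call in p53het rats were type 2 response (median 0.10, adjusted p = 0.166 with an estimated correlation), complement (0.18, adjusted p = 0.407 with an estimated correlation), macrophage (0.26, adjusted p = 0.2 with an estimated correlation), mast cell (0.88, adjusted p = 0.27 with an estimated correlation) and ciliated markers (0.28, adjusted p = 0.27 with an estimated correlation), all higher with Mitsui-7. Clock genes (-0.20, adjusted p = 0.2 with an estimated correlation), NK cell (-0.27, adjusted p = 0.27 with an estimated correlation), B cell (-0.23, adjusted p = 0.272 with an estimated correlation), endothelial (-0.26, adjusted p = 0.166 with an estimated correlation), erythroid (-0.48, adjusted p = 0.27 with an estimated correlation) and cardiac markers (-0.49, adjusted p = 0.255 with an estimated correlation) were lower. Over all genes 334 passed, 266 higher and 68 lower, and 260 differed at least 1.5-fold. A fixed block for slide gave 507 genes, including 316 of the 334, and 96.1% to 99.5% of genes called with a slide left out had the same direction on it (4 slides). Within slides the medians ran from 0.39 to 0.69 for extracellular matrix, 0.07 to 0.61 for mesothelial markers and -0.98 to -0.13 for neutrophil markers. The simulation recovered 32.8% of genes differing 1.5-fold.

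**Figure D3:**
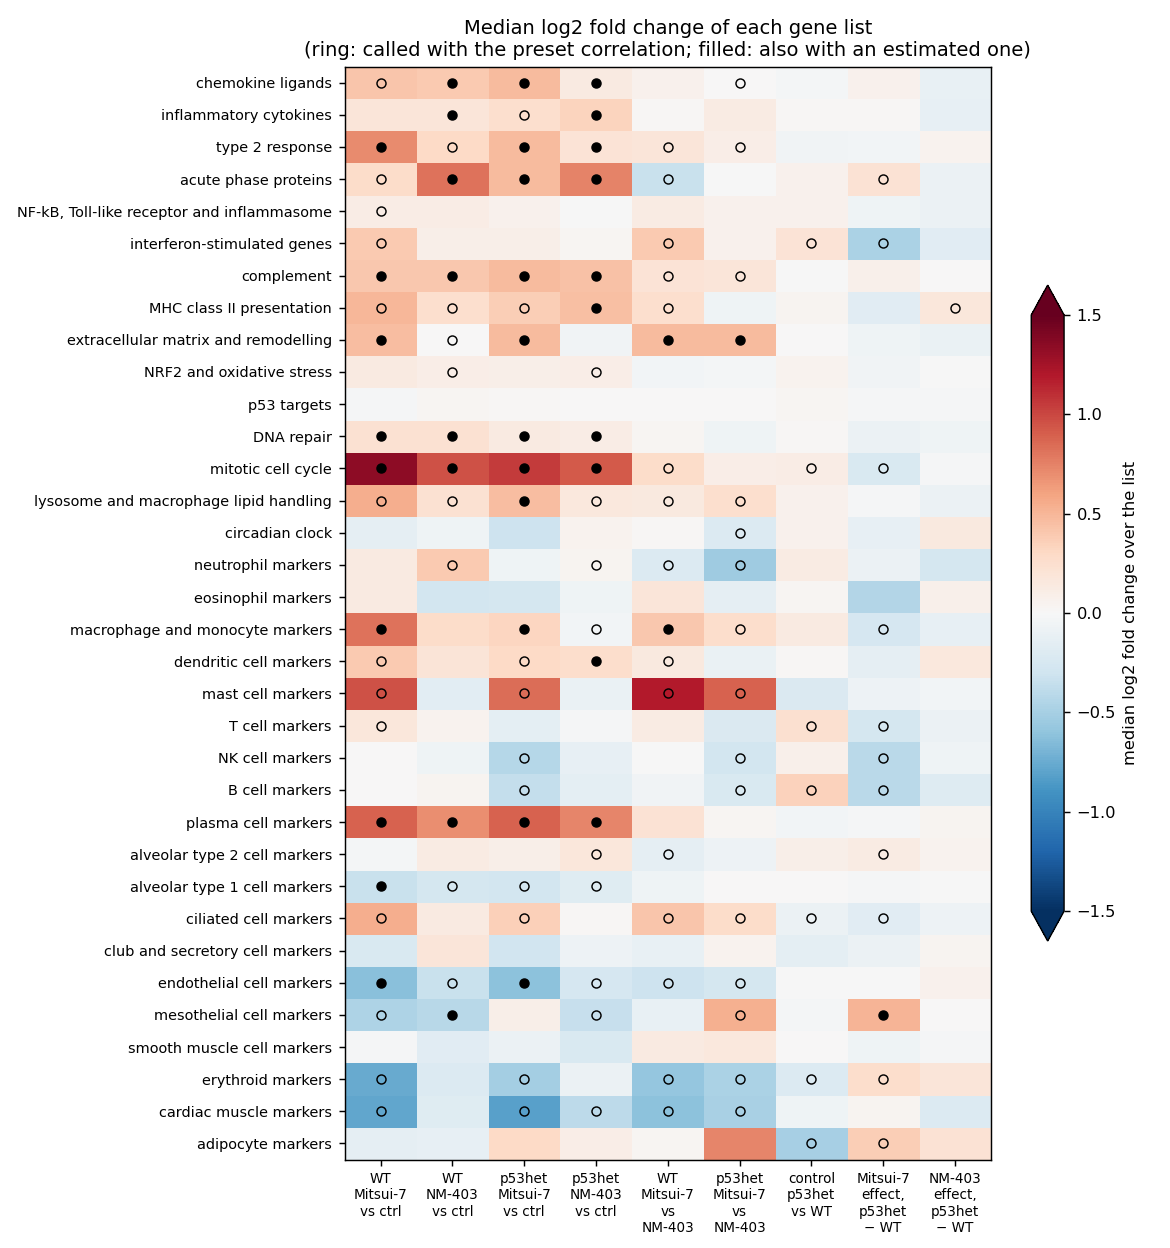
Median log2 fold change (colour) of each of 34 gene lists in 9 comparisons; an open ring marks a camera call with the preset correlation and a filled one a call also with an estimated correlation. The mitotic list had filled rings in all 4 exposure comparisons, with medians from 0.92 to 1.34.

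p53het control against WT control asks what the genotype changed without nanotubes. No gene passed in limma (0 of 24468, 483 at unadjusted p under 0.05, lowest adjusted p 1). Cdkn1a (0.01) and Mdm2 (0.02) differed little, and the p53 targets as a list did not pass (median 0.03, camera adjusted p = 0.0967). B cell markers (median 0.35, camera adjusted p = 8.33e-06, adjusted p = 0.14 with an estimated correlation), T cell markers (0.24, camera adjusted p = 1.13e-05, adjusted p = 0.224 with an estimated correlation) and interferon-stimulated genes (0.21, camera adjusted p = 3.22e-06, adjusted p = 0.234 with an estimated correlation) lay higher in p53het controls. The mitotic list did too (0.11, camera adjusted p = 0.0114, adjusted p = 0.639 with an estimated correlation). Adipocyte (median -0.50, camera adjusted p = 8.33e-06, adjusted p = 0.14 with an estimated correlation), erythroid (-0.21, camera adjusted p = 0.000636, adjusted p = 0.305 with an estimated correlation) and ciliated markers (-0.09, camera adjusted p = 0.00427, adjusted p = 0.305 with an estimated correlation) lay lower. Within slides the B cell median ran from 0.07 to 0.81, the interferon median from 0.02 to 0.47 and the adipocyte median from -0.73 to -0.36. The adipocyte score of WT_control replicate 2 was 2.27, against a WT control mean of 0.31 (SD 1.13) and a p53het control mean of -0.51 (SD 0.65). None of these lists passed in fry. The simulation recovered 44.8% of genes differing 1.5-fold and 93.9% of those differing 4-fold.

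The interaction terms ask whether either nanotube's effect differed between the genotypes. For Mitsui-7 no gene passed in limma (0 of 24468, 729 at unadjusted p under 0.05, lowest adjusted p 0.0954 for Fam25a, chosen after its value was seen, at 1.32 ± 0.24). Cdkn1a (-0.02 ± 0.16, adjusted p = 1) and Mdm2 (-0.20 ± 0.15, adjusted p = 1) did not pass. Mesothelial markers were called lower in WT rats (median -0.46, a call lost with an estimated correlation at adjusted p = 0.108, with Msln higher) and did not pass in p53het rats (median 0.09). Their median interaction was 0.51 (camera adjusted p = 1.05e-10), called with an estimated correlation too (adjusted p = 0.00441) but not in fry (adjusted p = 0.0647), with Upk1b at 1.21 ± 0.24 and 7 of 8 members above 0, Gpm6a at -0.21 being the other. No mesothelial member passed over all genes, and 3 did adjusted over the list alone (Upk1b, Upk3b and Msln). Interferon-stimulated genes had a median interaction of -0.48 (camera adjusted p = 5.72e-13), with adjusted p = 0.0772 with an estimated correlation; 7 of 23 were lower adjusted over the list alone, among them Ifit3 (-1.05 ± 0.37) and Isg15 (-0.84 ± 0.30). The p53 targets did not pass (camera adjusted p = 0.732), and their median of -0.02 and mean of -0.01 had the opposite sign to the test.

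A further 10 lists had a camera call for the Mitsui-7 interaction with the preset correlation only. Positive medians were found for acute phase proteins (0.22, adjusted p = 0.345 with an estimated correlation), alveolar type 2 (0.12, adjusted p = 0.411 with an estimated correlation), erythroid (0.26, adjusted p = 0.398 with an estimated correlation) and adipocyte markers (0.37, adjusted p = 0.257 with an estimated correlation). Negative medians were found for the mitotic list (-0.23, adjusted p = 0.569 with an estimated correlation) and for macrophage (-0.25, adjusted p = 0.319 with an estimated correlation), T cell (-0.26, adjusted p = 0.319 with an estimated correlation), NK cell (-0.40, adjusted p = 0.319 with an estimated correlation), B cell (-0.40, adjusted p = 0.319 with an estimated correlation) and ciliated markers (-0.17, adjusted p = 0.437 with an estimated correlation). In fry no list passed. Mean B cell scores differed more between the controls (-0.01 in WT, 0.22 in p53het rats) than with Mitsui-7 (-0.07 and -0.13). Within slides the mesothelial median ran from 0.24 to 0.43 and the interferon median from -0.72 to 0.02. The simulation recovered 17.9% of genes with a 1.5-fold difference in effect and 78.8% of those with a 4-fold difference.

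For NM-403 no gene passed as differing between genotypes in limma (0 of 24468, 413 at unadjusted p under 0.05, lowest adjusted p 0.983). Cdkn1a (-0.12 ± 0.17) and Mdm2 (-0.19 ± 0.15) did not pass. MHC class II presentation was the 1 list with a camera call (median 0.17, camera adjusted p = 0.0415, adjusted p = 0.96 with an estimated correlation), and its median within slides ran from -0.05 to 0.33. The simulation recovered 13.4% of genes with a 1.5-fold difference in effect and 77.3% of those with a 4-fold difference. With normexp background correction the median of all genes was -0.195 in this comparison, -0.154 in p53het NM-403 against control and 0.122 in p53het Mitsui-7 against NM-403.

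How far the responses had genes in common was asked in 4 pairs of comparisons; genes are not independent replicates, so the correlations carry no test. For Mitsui-7 in WT and p53het rats, which used separate controls, fold changes over 24468 genes correlated at r = 0.809 (Spearman 0.719). Genes called in both numbered 1055 higher and 826 lower, against 108.8 and 85.5 for independent lists, and Spp1, Mt3, Clca1 and Mmp12 were among those higher in both. For NM-403 the correlation was 0.477 (Spearman 0.341), with 245 higher and 20 lower in both against 7.2 and 0.6. A total of 212 genes rose and 14 fell in all 4 exposure comparisons, with Spp1, Mt3, Mmp12, Ccl7 and Retnla among the rises and Ucp3 among the falls.

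**Figure D4:**
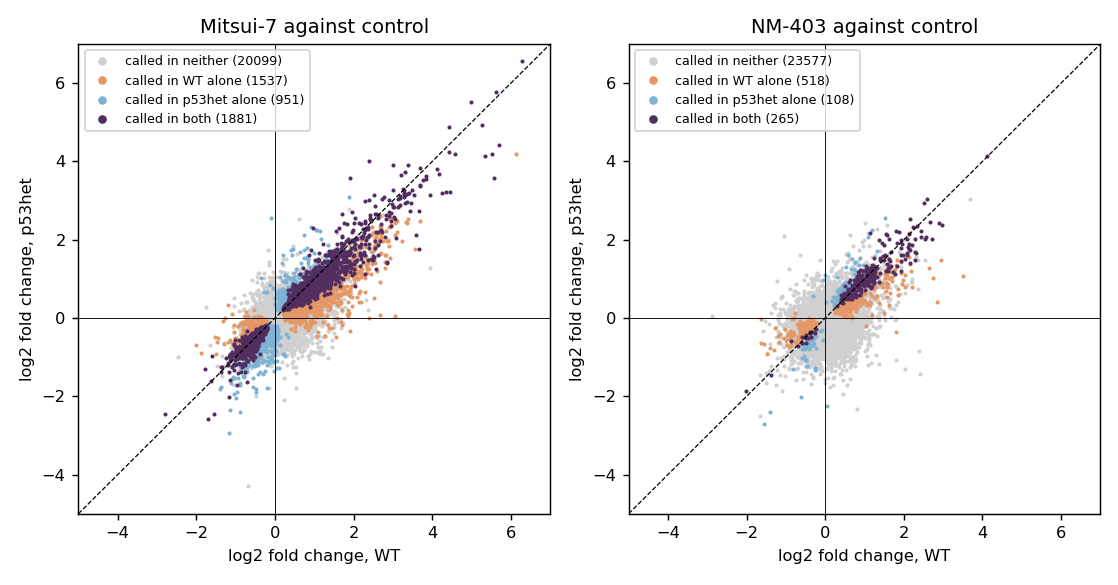
Log2 fold change against control in WT (horizontal) and p53het rats (vertical) for Mitsui-7 (left) and NM-403 (right); each point is 1 gene, coloured by the genotypes in which it was called. For Mitsui-7, 1055 genes were higher and 826 lower in both genotypes (purple).

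Mitsui-7 and NM-403 within one genotype were compared with the same controls, so part of their correlation comes from those controls. In WT rats r was 0.651 (Spearman 0.655), while simulated data without any effect gave a mean of 0.466 and a range from -0.111 to 0.841. Splitting the controls between the nanotubes gave a median r of 0.405. The covariance was 0.1205 against a simulated mean of 0.0353 and highest of 0.123, with 1 of 100 draws as high as the real value. Genes called in both numbered 422 higher and 168 lower; with split controls the medians were 175 higher and 26.5 lower, against 13.1 and 1.2 for independent lists. In the real lists 2 genes had opposite calls. These were Lpo (-0.98 with Mitsui-7, 1.45 with NM-403) and Lrg1 (-0.32 and 0.48), named after their values were seen. In p53het rats r was 0.531 (Spearman 0.468) against a simulated mean of 0.43 (0.032 to 0.743) and a split-control median of 0.162. Its covariance was 0.086 against a simulated mean of 0.0321 and highest of 0.1263, with 1 of 100 draws as high. There 271 genes were called higher and 45 lower in both; with split controls the medians were 111 and 5.5, against 5.6 and 0.7 for independent lists. Spp1, Mmp12, Retnla, Slc7a11, Il1rn and Ccne1 rose with both nanotubes in both genotypes.

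**Figure D5:**
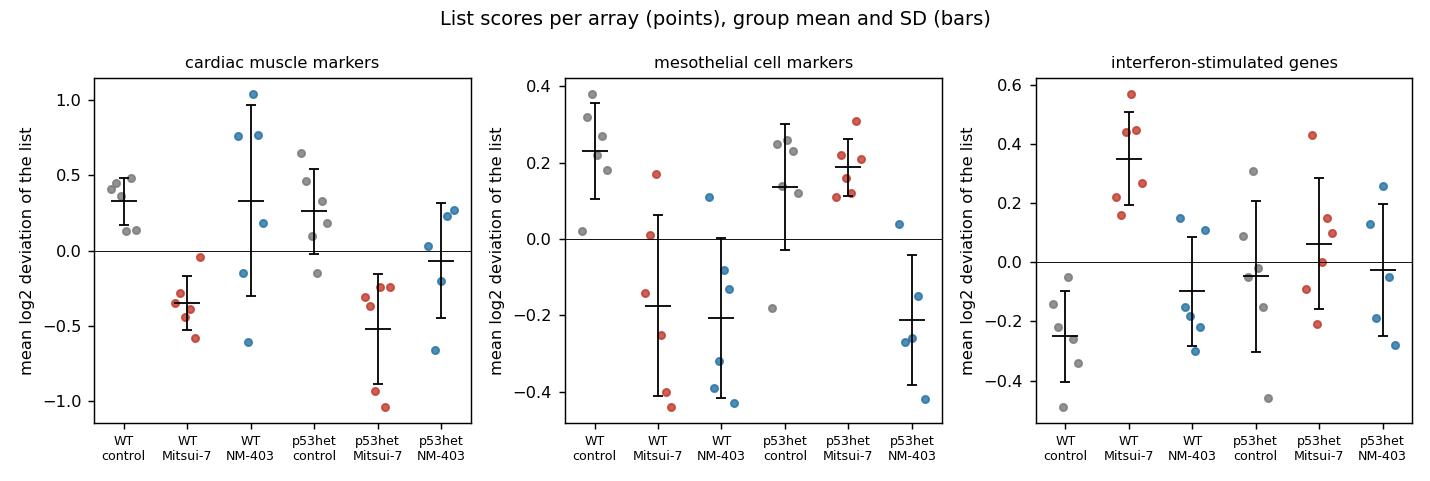
Mean log2 deviation of the cardiac, mesothelial and interferon-stimulated gene lists on each array (points) with group means and SD (bars). Cardiac scores averaged 0.33 in WT and 0.26 in p53het controls against -0.35 and -0.52 with Mitsui-7.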

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

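Of the tests given here, what the one that adjusts for B and T cells and the splits within slides would show was written before their results were seen; for the other tests it was written after. An array stood out when its gap to the nearest array of its group was a large part of the group's range, by Dixon's test, which chance meets in about 1 of 20 groups. It was met by 15 of 204 list scores (7.35%), 40 of 480 levels of named genes (8.33%) and 3 of 6 shares of spots above background. Values of the other arrays of the group are in brackets. A list stood out when a test of the interaction passed in camera.

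In the share of spots well above background, WT_Mitsui7 replicate 5 had 86.4% (71.2 to 73.8), WT_NM403 replicate 6 had 66.1% (71.3 to 73.6) and p53het_Mitsui7 replicate 3 had 73.7% (71.1 to 72.1).

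List scores stood apart in p53het Mitsui-7 for type 2 response on replicate 5, 0.61 (0.34 to 0.40), plasma cells on replicate 4, 0.70 (0.04 to 0.27), and adipocytes on replicate 6, 1.92 (-0.28 to 0.26). In p53het controls they did for extracellular matrix on replicate 6, -0.76 (-0.39 to -0.17), the clock on replicate 5, 0.68 (-0.09 to 0.06), alveolar type 1 cells on replicate 6, 0.45 (0.07 to 0.16), and mesothelial cells on replicate 1, -0.18 (0.12 to 0.26). In p53het NM-403 they did for DNA repair on replicate 3, 0.22 (0.07 to 0.11), plasma cells on replicate 4, -0.29 (0.22 to 0.40), and smooth muscle on replicate 2, -0.39 (-0.10 to -0.03). In WT NM-403 they did for the mitotic list on replicate 6, 0.64 (-0.03 to 0.16), and the clock on replicate 1, -0.18 (-0.09 to -0.04). In WT Mitsui-7 they did for neutrophils on replicate 6, -0.74 (-0.15 to 0.12), and alveolar type 2 cells on replicate 1, -0.30 (-0.12 to -0.04), and in WT controls for DNA repair on replicate 5, -0.27 (-0.21 to -0.18).

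Among levels, p53het_Mitsui7 replicate 1 lay towards the NM-403 groups in 5 genes: Orm1 -3.53 (-7.20 to -6.64), Cxcl6 -4.00 (-6.11 to -5.47), Lpo -2.51 (-3.82 to -3.35), Dhrs9 -1.25 (-2.54 to -2.08) and Cd5l -7.57 (-5.22 to -4.45). Its Spp1 (3.47) and Mmp7 (-0.99) did not, and whether an infection or a wrong label lies behind the 5 genes was not tested. Others of that group were Ccl1 -5.31 (-3.34 to -2.20), Cyp1a1 -7.11 (-9.44 to -8.82) and Spp1 2.85 (3.47 to 3.7) on replicate 6, and Ahrr -6.66 (-5.70 to -5.27) and RT1-O1 -4.27 (-0.86 to 0.53) on replicate 4. In p53het controls, replicate 6 stood apart for Alpk3 -1.89 (-1.33 to -1.09), Cd5l -7.35 (-9.45 to -8.81), Spp1 -4.66 (-3.00 to -2.18) and Tmem169 -2.93 (-4.51 to -3.92), replicate 1 for Cd177 1.08 (-0.11 to 0.12), and replicate 2 for Gcnt3 -8.22 (-9.77 to -9.20) and Upk3bl1 -8.92 (-6.87 to -5.98). In p53het NM-403 these were Sytl5 -5.61 (-7.12 to -6.83) and Tnn -7.10 (-4.39 to -3.42) on replicate 1, Alpk3 -2.64 (-2.35 to -2.26) on replicate 2 and Mest -4.32 (-3.97 to -3.92) on replicate 5. In WT Mitsui-7 they were Ccdc27 -6.42 (-7.54 to -7.17), Cpa1 -5.30 (-7.62 to -6.77) and Lrrc10 -8.90 (-8.08 to -7.76) on replicate 5, Mmp7 -3.47 (-1.76 to -1.26) and Retnla 2.30 (3.11 to 3.39) on replicate 1, and Tac1 -4.46 (-3.80 to -3.42) and Tmem169 -5.30 (-4.48 to -4.06) on replicate 2. In WT controls they were Fcgr3a -0.44 (-0.99 to -0.79), Psca -7.83 (-9.92 to -9.28) and Tnn -8.23 (-6.93 to -6.76) on replicate 5, Mdm2 -1.21 (-0.88 to -0.75) and Vom2r15 -6.11 (-5.24 to -4.88) on replicate 3, Esm1 -0.70 (0.47 to 0.85) on replicate 2, RT1-O1 0.12 (-0.84 to -0.69) on replicate 6 and Ucp3 -4.13 (-3.26 to -2.92) on replicate 1. In WT NM-403 they were Ihh -3.77 (-4.61 to -4.30) and Muc4 -5.59 (-3.64 to -3.15) on replicate 3, Myh7 1.31 (-1.08 to -0.51) on replicate 5 and Wnt2b -4.34 (-5.02 to -4.94) on replicate 1.

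The Mitsui-7 effect differed between genotypes in camera for 12 lists, by median: mesothelial 0.51, interferon-stimulated -0.48, NK -0.40, B -0.40, adipocyte 0.37, T -0.26, erythroid 0.26, macrophage -0.25, mitotic -0.23, acute phase 0.22, ciliated -0.17 and alveolar type 2 0.12. With an estimated correlation 11 of these 12 calls were lost, in fry all 12, and by permutation of list scores 0 of 34 lists passed after adjustment. The NM-403 effect differed in camera for MHC class II, 0.17, a call lost with an estimated correlation (adjusted p = 0.96) and in fry.

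Mesothelial markers passed as lower in WT Mitsui-7 lungs, although Msln rose and the call was lost with an estimated correlation (adjusted p = 0.108), and did not pass in p53het ones, with an interaction of 0.46 ± 0.14 in the mean list score. A block for slide left the value at 0.43 ± 0.13, which argues against slide as the whole cause, and it ran from 0.39 to 0.52 with 1 array left out. Permutations that did not keep to slides gave an exact p of 0.00407 and, adjusted over 34 lists, 0.126. Random differences between lobes in how much pleura was sampled therefore stay open. A difference in the mesothelial response between genotypes may exist but was not separated from that.

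Cardiac markers were lower with Mitsui-7 in both genotypes by -0.73 ± 0.15, with Myh6 and Mybpc3 lower in both. The list calls in WT and p53het rats were lost with an estimated correlation (adjusted p = 0.0982 and 0.107). Blocked on slide the value was -0.77 ± 0.16, which argues against slide. The permutation p, adjusted over 34 lists, was 6.64e-06 (the unadjusted 2.34e-06 is the smallest these permutations can give), which argues against random differences between lobes. Smooth muscle markers changed by -0.07 ± 0.07 and lay 0.65 ± 0.14 above the cardiac ones, and alveolar type 2 markers changed by 0.02 ± 0.06. This argues against an even dilution by cells that entered the lung. Other resident lists did fall with Mitsui-7. Endothelial scores went from 0.28 to -0.29 in WT and from 0.29 to -0.26 in p53het rats. Alveolar type 1 scores went from 0.17 to -0.11 in both, so a part for dilution stays open. A lower share of vein-associated heart muscle in exposed lobes, through dissection or through the exposure, could account for the cardiac fall. No value here decides between these.

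Interferon-stimulated genes passed in camera as higher in WT Mitsui-7 lungs (10 of 23 genes) and did not in p53het ones. With an estimated correlation the calls in WT (adjusted p = 0.0898) and for the interaction (adjusted p = 0.0772) were lost, the latter in fry too. The interaction of the mean list score was -0.49 ± 0.17, and -0.51 ± 0.15 with slide as a block, which argues against slide. Mean scores were -0.25 in WT and -0.05 in p53het controls, and 0.35 and 0.06 with Mitsui-7. A part of the interaction thus came from the controls. The exact permutation p adjusted over 34 lists was 0.126, from permutations that did not keep to slides, so random differences between rats stay open. With the B and T cell score as a covariate the interaction was -0.33 ± 0.16, which neither excludes nor shows a part for these cells. A genotype difference might underlie the rest.

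Splits of the arrays into other groups, 100 per comparison, gave as many called genes as the real groups in 1 case, the real one, for WT Mitsui-7 (3418, highest other 1601), WT NM-403 (783, 397), p53het Mitsui-7 (2832, 885), WT Mitsui-7 against NM-403 (814, 124) and p53het Mitsui-7 against NM-403 (334, 65). This is the lowest share 100 splits can give, and they did not keep to slides. They make chance unlikely there but cannot exclude it. Other splits had a median of 0. The highest were near the real groups, most with labels swapped, so they held the real effect. For p53het NM-403, 2 splits gave as many, the real one included (373, highest other 3690). The 3690 split parted slides 1 and 5 from 2, 3 and 4, which points to a structure by slide. Labels were therefore also exchanged only within slides, in every way, with slide as a block. For p53het NM-403 the real split then gave the most genes of 48 (960, highest other 283). It did so too for WT Mitsui-7 (5430, highest other 1434 of 72 splits), WT NM-403 (1892, 111 of 72), p53het Mitsui-7 (5521, 3823 of 72) and Mitsui-7 against NM-403 in WT (1538, 248 of 54) and p53het rats (507, 1 of 36). With only 36 to 72 splits each, these ranks make chance within slides unlikely but cannot exclude it. For p53het against WT controls and for both interactions the real count was 0 (highest others 3, 1 and 1). Every split reaches 0, so these say nothing about chance.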

How the results depend on the processing

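Of the settings given here only the model without 2 arrays (WT_Mitsui7 replicate 5 and p53het_control replicate 6) was chosen after the data were seen. Counts of called genes follow the order WT Mitsui-7, WT NM-403, p53het Mitsui-7, p53het NM-403, then Mitsui-7 against NM-403 in WT and in p53het rats. They were 3418, 783, 2832, 373, 814 and 334. Slide as a fixed block gave 5430, 1892, 5521, 960, 1538 and 507, and as a random block 5419, 1901, 5146, 981, 1541 and 581. Both blocks take the spread between slides into account. The authors' values (9803 genes) gave 1739, 463, 1418, 160, 329 and 142. An adjusted p under 0.01 gave 1752, 334, 1438, 173, 419 and 189, and a fold of at least 1.5 gave 1976, 448 and 1514 in the first 3. Array weights gave 1448 for WT NM-403, 5239 and 2393 for p53het Mitsui-7 and NM-403, and 937 for the p53het contrast of the nanotubes. Normexp gave 1797 and 191 for p53het Mitsui-7 and NM-403 and 443 for the WT contrast of the nanotubes. Models of only the groups compared gave 1715, 145 and 499 for the same 3. For the authors' values the set of probes and the scaling changed together and were not separated, and except for the blocks and thresholds the cause was not tested. Leaving out 1 array gave 2285 to 3885, 459 to 936, 2054 to 3304, 227 to 618, 553 to 936 and, for the p53het contrast of the nanotubes, 234 or more. The low of 459 came without WT_NM403 replicate 6; without p53het_NM403 replicates 1, 2, 3 and 5 the count was 618, 227, 234 and 231. A replicate block, although the numbers were not taken to pair the arrays, gave 3536, 753, 2913, 348, 822 and 330. Without the 2 arrays the counts were 2867, 866, 3439, 373, 594 and 379.

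The contrast of controls stayed at 0 genes in limma (483 at unadjusted p under 0.05) under every alternative. The Mitsui-7 interaction rose from 0 (729 unadjusted) to 2 genes with array weights and to 2 with slide as a random block, Adgrd1 (0.92 ± 0.16 with the block) and Fam25a (1.33 ± 0.23), and to 1, Fam25a (1.45 ± 0.22), without p53het_Mitsui7 replicate 6; with 1 array left out its range was 0 to 1. For NM-403 it was 0 (413 unadjusted), 0 to 0 with 1 array left out, and 1 without the 2 arrays, a probe without a gene symbol (0.97 ± 0.15). These genes were chosen after their values were seen.

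The correlation of Mitsui-7 effects between genotypes, 0.809, was 0.895 with the authors' values and 0.654 without a filter on dim probes, and 0.774 to 0.818 with 1 array left out. Other correlations ran, with 1 array left out, from 0.357 to 0.552 for NM-403, 0.554 to 0.705 between nanotubes in WT rats and 0.397 to 0.64 in p53het rats.

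Camera called 22, 16, 21, 19, 17 and 16 lists in the 6 contrasts, 7 between controls, 12 for the Mitsui-7 and 1 for the NM-403 interaction. With an estimated correlation these were 9, 8, 11, 10, 2, 1, 0, 1 and 0. In fry they were 25, 16, 21, 13, 16, 9, 0, 0 and 0. Quantile normalization gave 11 between controls, the authors' values 6 for the Mitsui-7 interaction, and array weights 9 for the p53het contrast of the nanotubes. The NM-403 interaction had 7 lists with normexp, 2 without a filter, and 0 with quantile, median, authors' values, stricter background, mean of probes, weights, replicate block or without the 2 arrays. No called list changed direction under these settings. Of the values of named genes 2 reversed: Rtkn2 in WT Mitsui-7 lungs with the mean of all probes (0.04) and Cenpe in p53het NM-403 lungs with normexp (-0.02). The values of named genes numbered 509, some of which had no call to lose. Of these 108 lost their call in models of only the groups compared, 86 with normexp, 19 with a replicate block and 3 with slide as a fixed block. Calls lost under at least 1 setting other than leaving out an array were 22 of 122, 25 of 69, 39 of 114, 35 of 55, 36 of 77 and 18 of 49 in the 6 contrasts. Signal over background limits the folds of dim genes; Cenpe, for example, was above background on 0 of 6 p53het control arrays.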

Other observations

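The families and genes named here were chosen after their values were seen, so no test of a family is given. Genes of mucous epithelium rose with Mitsui-7: of 10 measured members of a list put together by hand 8 rose in each genotype (median log2 2.27 in WT and 2.03 in p53het rats). Ern2, an endoplasmic reticulum sensor of goblet cells, rose by 3.68 ± 0.22 in WT and, with 2 of 6 controls above background, by 3.40 ± 0.22 in p53het rats. With NM-403 the list's median was 0.76 in WT and 0.62 in p53het rats, and 1 and 3 members passed as higher. Lgals4, the epithelial oxidase gene Duox2, Acod1, which makes itaconate in macrophages, and Ido1, which degrades tryptophan, were called higher with Mitsui-7 in both genotypes; no more than 1 of 6 arrays of either control group was above background for any of them, so no fold is given.

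Some enzymes of foreign compound metabolism fell with Mitsui-7. Of 20 glutathione S-transferase names 5 fell in each genotype (median -0.23 in both), Gsta3 by 1.05 (SE 0.21) in WT and 1.17 (SE 0.21) in p53het rats. Flavin monooxygenases fell for 3 of 6 in WT and 2 of 6 in p53het rats (medians -0.87 and -0.62), Fmo2 among them (-0.97 ± 0.24 and -1.05 ± 0.24). Of 52 cytochrome P450 names 8 fell and 1 rose in each genotype. The medians of these 52 were 0.01 and -0.09. With NM-403 1 glutathione S-transferase fell in WT rats and none in p53het rats. Whether these falls differ between genotypes was not tested by family.

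The adipocyte score was 2.27 on WT_control replicate 2 and 1.92 on p53het_Mitsui7 replicate 6, and no higher than 0.94 on any other array.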
